A study of Homo sapiens with 4 samples.

How the data were processed

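RNA from 4 samples of IMhu-M cells was sequenced: 2 libraries of cells left untransfected and 2 libraries of cells that received ANKRD55 mRNA with a Viromer transfection reagent and were incubated for 24 hours. Groups and replicate numbers were taken from the sample titles. RNA was isolated with a column kit and libraries were made with a low-input kit, per the labels' protocols.

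Per the submitters' processing notes, TopHat2 2.1.0, SAMtools 1.2, Picard 2.9.0, Cufflinks 2.2.2 and DESeq2 were used with genome build GRCh38. The role and order of these tools, the gene annotation, the tool that counted reads, the strand setting and any filter are not given in the sources used here. The authors deposited 1 table with 60664 rows and 4 value columns, 1 column per library, matched to the sample titles through the column names. No column of the table belonged to any other sample.

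The table pairs no row with a gene name or identifier. Rows were therefore identified by their position in the table, counted from 1 below the header, and no gene name was inferred from that position. For this reason the level of ANKRD55, the 36 gene lists fixed before the data were examined and the coordinates of the rows were not analysed here. The rule for named genes was to give the genes with the largest changes past the threshold. It also required both transfected libraries to lie on one side of both untransfected libraries and a mean of at least 5 CPM in 1 group. It was applied to rows, and 34 rows passed it. The plan called for more of them to be named, but only the 2 rows with the largest rise are given by position.

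The deposited values are normalized counts, that is, read counts divided by a size factor per library. This was tested on the table: within a tolerance of 0.0015, 100% of the values in every column were whole multiples of one step, and the step was 1.08 and 0.736 in untransfected replicates 1 and 2, and 0.993 and 1.09 in transfected replicates 1 and 2. Size factors recomputed from the recovered reads as the median ratio to the geometric mean, over rows with a read in every library, differed from the inverse of these steps by 0% to 4 decimals. The table writes decimals with commas. One cell of its last row held a stray character; the other cells of that row were 0 and the cell was read as 0.

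The design fixed before the data were examined assumed a table of counts and named a log-scale test for a table of normalized values, which was used here. Count models of the negative binomial kind were not run, although whole reads could be recovered, and limma-voom was the test on the recovered reads. The main test was limma 3.58.1 (R 4.3.3) with an intensity-dependent trend on log2(normalized count + 1), with the group as the only term, over rows with a value of at least 1 in at least 2 libraries. P-values are two-sided with Benjamini-Hochberg adjustment, and the threshold was 0.05. A fold change is on the log2(value + 1) scale, which understates the change of rows with few reads. With 2 libraries per group the model had 2 residual degrees of freedom, to which limma added 4.15 prior degrees of freedom shared among rows. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 read the table and drew the plots.

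The recovered reads summed to 230608904 and 333571380 in untransfected replicates 1 and 2, and to 220512135 and 199016962 in transfected replicates 1 and 2. Intervals on shares of reads are exact Clopper-Pearson 95% intervals and cover counting error only, since reads without molecular identifiers are not independent molecules.

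The test was checked on simulated data: reads were drawn from the table's row means and size factors with a log2 spread between replicates of 0.377, and 200 rows were raised by known folds. Over 37199 rows tested, 47 of 50 rows raised 4-fold and 50 of 50 rows raised 16-fold, 64-fold and 256-fold were recovered, with 2 false calls. Over 14862 simulated rows with a mean of at least 1 CPM, 44 of 50 rows raised 4-fold were recovered, with 6 false calls. The simulated spread was equal for all rows and lower than that of the data: it gives a standard deviation of the log2 difference between 2 libraries of 0.533, against 1.06 and 1.15 between the untransfected and the transfected replicates. The simulated recovery therefore overstates the power of the real comparison, and the false calls hold only for that equal spread. The raised rows all had a mean of at least 100 normalized counts, and no row was lowered. The check therefore does not cover falls or rows that start near 0.

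Alternatives planned before the data were examined were a pseudocount of 0.1, no filter except rows at 0 everywhere, a mean of at least 1 CPM, scaling by library size, upper quartile scaling, limma-voom on the recovered reads, a minimum of 2-fold, the replicate number as a block, and leaving out each library in turn. The plan also held a negative binomial main test for a table of counts and another negative binomial test as an alternative, and neither was run. The fits that combine the 1 CPM filter with voom, the block or a left-out library were added after seeing the data, as were the counts of rows by fold limits and the comparison of separate pairs of libraries. The model without pairs was planned before the data were examined, since no source says that replicate numbers mark shared days. The replicate numbers were then checked for pairing. Deviations of same-numbered libraries from their group means correlated at -0.04 over 18686 rows, which gave no reason to treat the numbers as pairs.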

Results

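The data are RNA sequencing libraries of IMhu-M cells, a line of human microglia immortalized with SV40. Microglia are the resident immune cells of the central nervous system. ANKRD55 is a gene that codes for a protein with ankyrin repeats and lies in a region associated with multiple sclerosis risk. The series holds 2 groups with 2 libraries each: cells left untransfected and cells transfected with ANKRD55 mRNA for 24 hours. The submitters call the replicates biological. The labels do not say whether they came from separate cultures, so p-values measure the spread between these libraries only. None of the 4 libraries received the reagent alone or another mRNA, so the comparison covers the reagent, the delivered RNA and the ANKRD55 product together.

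Untransfected replicates 1 and 2 held 230608904 and 333571380 reads, and transfected replicates 1 and 2 held 220512135 and 199016962 reads. At least 1 read fell on 31202 and 32917 rows of the table in the untransfected libraries, and on 34979 and 34666 rows in the transfected libraries, which had fewer reads. Another 19116 of the 60664 rows were at 0 in every library. The deposited table gives a normalized count per row and no gene name, so results are given by row, and the level of ANKRD55 was not analysed here.

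The comparison of transfected with untransfected cells asks which transcripts change after ANKRD55 mRNA is introduced. The few rows past the threshold all rose by at least 27.2-fold after transfection, and 14 of them started from almost no reads. This fold is the smallest rise among the rows that passed and not a limit set beforehand. Large rises were also seen in rows that did not pass: 450 of 18686 rows with a mean of at least 100 normalized counts were at least 8-fold higher. In limma's test on log2(normalized count + 1), 34 of 34019 rows tested were higher in transfected cells and 0 were lower at a Benjamini-Hochberg adjusted p under 0.05. Each of the 34 had both transfected libraries above both untransfected libraries. Their rises ranged from 27.2-fold to 381928-fold with a median of 815-fold. Of the 34 rows, 14 had fewer than 20 normalized counts in both untransfected libraries, and 4 had an untransfected mean of at least 1000. In transfected cells the values of the 34 rows lay between 1937 and 6742244 normalized counts. In untransfected cells they lay between 0 and 4284. Adjusted p in limma's test ranged from 0.0027 to 0.043 over these rows. For 2 rows with 0 reads in both untransfected libraries the rise was at least 2874-fold and at least 5576-fold, taking 3 reads over the group as the floor, and the median of the 34 rows with these at their bounds was again 815-fold.

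**Figure D1:**
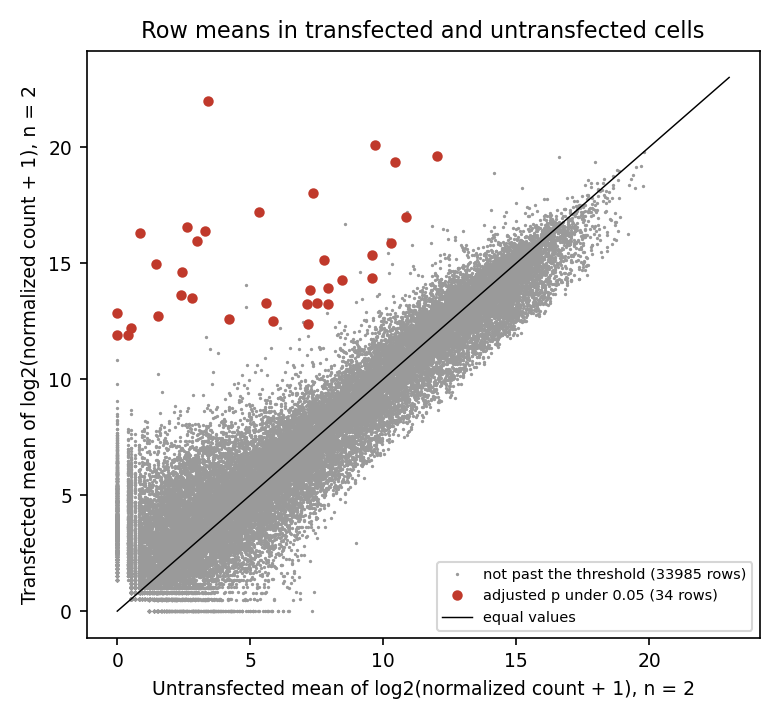
Mean log2(normalized count + 1) of each tested row in untransfected cells (horizontal axis, n = 2) and transfected cells (vertical axis, n = 2), with the line of equal values. The 34 rows past the threshold (red) lie above the line, between 1937 and 6742244 normalized counts in single transfected libraries.

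The row with the largest rise, row 11366 of the table, held 5 and 23 reads in untransfected replicates 1 and 2. It held 6790794 and 2276481 reads in transfected replicates 1 and 2. Its normalized count rose from 11.2 ± 8.14 (SD, n = 2) to 4616595 ± 3006122 (SD, n = 2). The log2 fold change was 18.54 with a standard error of 0.69 and an adjusted p of 0.0027 in limma's test. This row alone took 3.08% of all reads in transfected replicate 1 (95% Clopper-Pearson interval 3.077 to 3.082%) and 1.14% in transfected replicate 2 (1.142 to 1.145%). It was the most abundant row of both transfected libraries. The most abundant row of untransfected replicate 1 took 0.450% of its reads, and that of untransfected replicate 2, a different row, took 0.480%. Whether the reads of row 11366 came from the delivered mRNA itself was not analysed here.

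The row with the next largest rise, row 7014, held 0 and 3 reads in untransfected replicates 1 and 2. It held 111964 and 52166 reads in transfected replicates 1 and 2. Its normalized count rose from 1.10 ± 1.56 (SD, n = 2) to 84122 ± 38242 (SD, n = 2). The log2 fold change was 15.44 with a standard error of 0.78 and an adjusted p of 0.0045 in limma's test. With a pseudocount of 0.1 in place of 1 the log2 fold change was 17.34 and the adjusted p in limma's test was 0.113, which ended the call. The ratio of its pooled share of reads was 73574, with an exact 95% counting interval from 25175 to 356769.

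**Figure D2:**
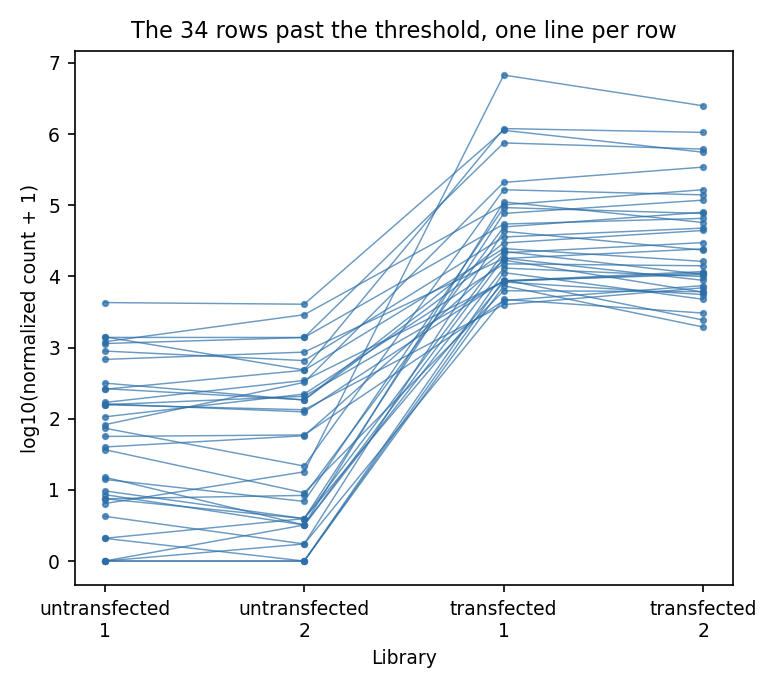
Normalized counts of the 34 rows past the threshold in each library, as log10(normalized count + 1), with 1 line per row. No row exceeds 4284 in an untransfected library, and none is under 1937 in a transfected library.

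Together the 34 rows took 0.0052% and 0.0057% of the reads in untransfected replicates 1 and 2. They took 5.03% and 2.79% in transfected replicates 1 and 2. Without row 11366 the shares of the remaining rows in transfected replicates 1 and 2 were 1.95% and 1.64%. Over all 60664 rows of the table, and not the 34 alone, a switch from near 0 to a high level was seen in one direction. Under 10 normalized counts in both untransfected libraries and at least 1000 in both transfected libraries were found in 13 rows, and the opposite was found in 0 rows. Most but not all of the 13 rows were among the 34, so this count is not separate evidence. The other ways of dividing the 4 libraries into pairs gave 0 such rows in either direction. Those pairs mix transfected and untransfected cells, so rows that differ between the groups cannot be counted there.

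Changes of at least 2-fold went both ways. Among 18686 rows with a mean of at least 100 normalized counts, 987 rows were at least 2-fold higher in both transfected libraries than in both untransfected libraries, and 1182 rows were at least 2-fold lower. The first of the other divisions of the libraries into pairs, by replicate number, gave 69 and 62 rows. The other gave 177 and 80 rows. In both, each pair mixes transfected and untransfected cells, so a group difference lowers these counts and they are not a chance baseline. By the mean log2 change, 450 of the 18686 rows were at least 8-fold higher and 96 were at least 8-fold lower. These counts apply a limit on size and no test, and they include the 34 rows above. In limma's main test the lower rows did not pass. The lowest adjusted p of a lower row in limma's test was 0.178, and limma-voom with the main filter also called 0 lower rows. Over rows with a mean of at least 1 CPM, limma-voom called 591 higher and 1033 lower rows. The balance of directions at an unadjusted p under 0.05 depended on the scaling. There limma's main test had 3152 higher and 2246 lower rows. Scaling by library size gave 3786 and 1663, and upper quartile scaling gave 3231 and 2383. The 2-fold counts and the 1 CPM fits were not repeated with another scaling. With no effect, a share of 0.05 of the 34019 rows tested is expected at that unadjusted limit.

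The number of rows called depended on the pseudocount, the test and the filter. With the main filter, limma with a pseudocount of 0.1 called 17 rows and limma-voom called 60, all higher. With rows of a mean of at least 1 CPM only, limma called 434 higher and 671 lower rows among 15856 tested, and all 34 rows of the main test were among them. The called lower rows in that fit had log2 fold changes from -3.53 to -1.68 with a median of -2.43. The called higher rows had log2 fold changes from 1.68 to 18.54 with a median of 2.60. With the main filter, leaving out any 1 of the 4 libraries left 0 rows past the adjusted threshold in limma's test, with 1 residual degree of freedom. At an unadjusted p under 0.05 these fits had 1722 higher and 516 lower rows without untransfected replicate 1, and 3114 higher and 363 lower rows without untransfected replicate 2. They had 3816 higher and 4766 lower rows without transfected replicate 1, and 2547 higher and 1768 lower rows without transfected replicate 2. With the 1 CPM filter limma called 131 and 358 rows without untransfected replicates 1 and 2, and 5116 and 280 rows without transfected replicates 1 and 2. At the unadjusted limit a share of 0.05 of rows is expected with no effect, so the unadjusted counts are not counts of changed rows. In each fit that left out a library, 1 group had a single library, which was assumed to vary like the other group. Without either untransfected library the 1 CPM fits had an infinite prior, so the 4 counts do not measure stability alike.

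The direction of change was shared by separate pairs of libraries. The log2 change of transfected replicate 1 from untransfected replicate 1 correlated with that of transfected replicate 2 from untransfected replicate 2 (Pearson's r = 0.51, Spearman's rho = 0.50). With the controls exchanged, Pearson's r was 0.60 and Spearman's rho was 0.62. These correlations run across 18686 rows, which are not independent replicates. Of the 3492 rows at least 2-fold higher in the first pair, 74.9% were also higher in the second pair, against 50.6% of all rows. Of the 2423 rows at least 2-fold lower in the first pair, 82.5% were also lower in the second pair, against 49.4% of all rows.

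**Figure D3:**
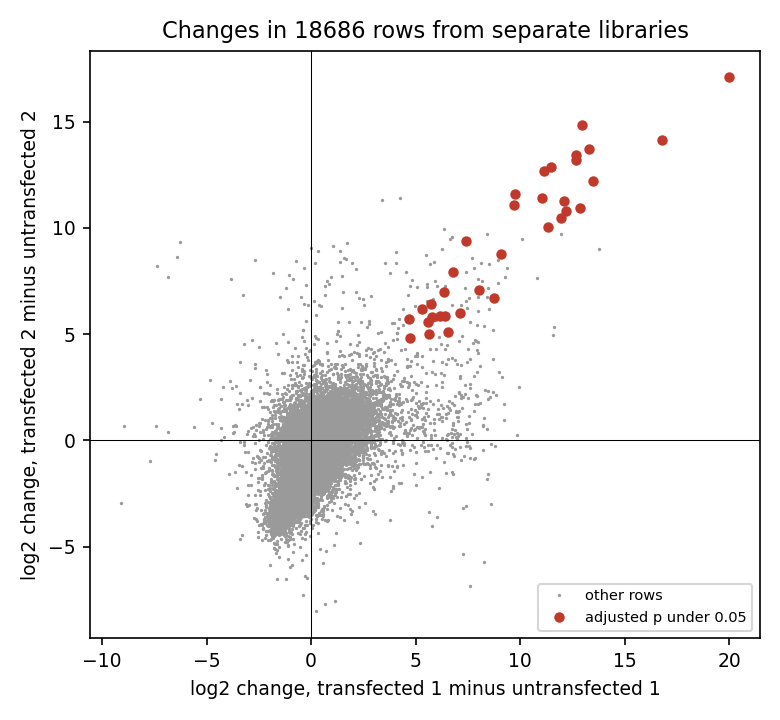
Log2 change of 18686 rows in transfected replicate 1 minus untransfected replicate 1 (horizontal axis) and in transfected replicate 2 minus untransfected replicate 2 (vertical axis). Red points are rows past the threshold, all higher in both pairs, and the remaining rows (grey) extend to the upper right and the lower left (Pearson's r = 0.51 over all rows).

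The replicates of each group were separate libraries and not copies of one. Among the 18686 rows, 15.9% differed by more than 2-fold between the untransfected replicates and 34.9% between the transfected replicates. Transfected replicate 1 differed by more than 2-fold from untransfected replicates 1 and 2 in 31.7% and 20.9% of rows. Transfected replicate 2 differed from them in 51.1% and 45.7% of rows. The standard deviation of the log2 difference was 1.06 between the untransfected replicates and 1.15 between the transfected replicates. It was 1.17 between untransfected replicate 2 and transfected replicate 1, and 1.91 between untransfected replicate 1 and transfected replicate 2. By the share of rows over 2-fold, transfected replicate 1 lay closer to both untransfected libraries than to transfected replicate 2 (34.9%). By the standard deviation it lay about as far from untransfected replicate 2 as from transfected replicate 2 (1.17 and 1.15). The libraries thus did not separate clearly by group on these measures.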

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

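Every alternative kept row 11366 and row 7014 higher after transfection, with log2 fold changes from 17.80 to 19.28 and from 14.60 to 17.34 over the 17 alternatives that gave a value. Their adjusted p stayed under the threshold in 13 and 12 of these, and reached 0.339 and 0.312 at most. The 34 calls became 17 with a pseudocount of 0.1 (row 7014 had an adjusted p of 0.113 there) and 60 with limma-voom, which called 33 of the 34. Scaling by library size, upper quartile scaling and no filter gave 39, 47 and 44, each including the 34, and a minimum of 2-fold gave 34. No lower row was called in any of these fits. A mean of at least 1 CPM gave 1105 calls, 671 of them lower, and with that filter limma-voom gave 1624, 1033 of them lower. Leaving out each library in turn gave from 0 to 0 calls with the main filter. With the 1 CPM filter, leaving out untransfected replicate 1 or 2 gave 131 or 358 calls (29 or 41 lower), and leaving out transfected replicate 1 or 2 gave 5116 or 280 (3464 or 153 lower). The replicate block gave 2371 calls, 1143 of them lower, and with the 1 CPM filter 1812, of which 1191 were lower. Same-numbered libraries did not deviate together (correlation -0.04), and the block left 1 residual degree of freedom with an infinite prior in limma, so its counts are given for completeness. The prior was also infinite without either untransfected library under the 1 CPM filter. Relative to the deposited scaling, scaling by library size moved the median row by 0.18 on the log2 scale and upper quartile scaling by 0.02. The planned negative binomial tests, the level of ANKRD55 and the gene lists were not run.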

Other observations

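Of the tests here, the one of the scaling and those on rows changed by at least 2-fold in transfected replicate 1 were chosen after the result was seen.

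The transfected replicates were compared in rows picked by their transfected mean, a choice that includes replicate 2 itself and so favours rows where replicate 2 is extreme. Among the 3649 rows at least 2-fold lower in that mean, 4.52% were higher in replicate 2 than in replicate 1, and the median difference was -1.60 on the log2 scale (quartiles -2.06 to -1.07). Among the 2958 rows at least 2-fold higher, 68.7% were higher in replicate 2, with a median difference of 0.42 (quartiles -0.21 to 0.85). Among the 12079 rows that changed by less than 2-fold the median difference was 0.15. Which genes these rows hold was not analysed here.

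Transfected replicate 2 lay farther from the untransfected libraries than replicate 1. Its lower depth does not account for this. After every library was thinned to 199016962 reads, replicate 2 differed by over 2-fold from the controls in at least 45.3% of rows, above the 30.8% that was the highest for replicate 1. A candidate explanation is a larger fall of the same transcripts in replicate 2. In the 1901 rows at least 2-fold lower in replicate 1, where picking on replicate 1 works against it, replicate 2 was lower still by a median of -1.27 (quartiles -1.92 to -0.27). In the 96 rows at least 8-fold lower in the transfected mean the median was -2.28, but the 40 rows picked at that limit on replicate 1 alone were higher in replicate 2 by a median of 4.32, so these rows leave it open. A larger rise stays open as well. The median was 0.31 in the 450 rows at least 8-fold higher in the transfected mean, but -0.20 in the 433 rows picked at that limit on replicate 1 alone, and it was -0.027 in the 2801 rows at least 2-fold higher in replicate 1. A difference in uptake of the RNA, in cell state or in RNA quality between the transfected samples was not tested.

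All rows called with the main filter were higher after transfection. A change of scaling brought about by abundant rows was too small to account for the rises of the 34 rows. Under another scaling their smallest log2 fold change was 4.79, while the median row moved by at most 0.18. The 34 rows were picked for large rises, so their sizes cannot tell why no lower row was called. The main test called no row with a log2 rise under 4.76. With the 1 CPM filter the largest called fall was -3.53, and the 434 called rises had a median of 2.60. Most of those rises did not pass the main test either, so the split of 34 to 0 does not show that the change went one way. Library size and upper quartile scaling also called 0 lower rows. Only 1 of the 3 ways to divide the 4 libraries into pairs, the real one, called any row (34 rows, against a highest count of 0 in the others), and 3 divisions are too few for a share under 0.05. With the 1 CPM filter the real division called 1105 rows and the others 0. Each pair of the other divisions mixes transfected and untransfected cells. A group difference would thus widen the spread within those pairs, so their counts of 0 do not measure chance. Whether the reagent, the delivered RNA or the ANKRD55 product raised these rows was not tested, since none of the 4 libraries received the reagent alone. Because rows carry no gene name, reads of the delivered mRNA itself were not told apart from transcripts made by the cells.

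The number of rows called rose from 34 to 1105 once rows with a mean under 1 CPM were left out. Adjusting the main p-values over the 15856 kept rows alone gave 57 calls, so a shorter list to adjust for was not the whole cause. The prior degrees of freedom rose from 4.15 to 12.2, so limma shared the spread among the kept rows more strongly. Whether the shared spread itself became narrower was not tested.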
